A study of Homo sapiens with 10 samples.

How the data were processed

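Gene expression and guide RNAs were read in single neurons differentiated from the WTC11 line, in 5 transcriptome libraries and 5 guide-enriched libraries that share replicate numbers. Per the submitters' processing notes, the authors ran Cell Ranger 7.0.0 on the hg38 genome. The deposited values are counts, that is, UMIs per feature and cell barcode, without normalization, over genes and 64 guide features in each of the 5 matrices. Barcodes had been filtered by the authors to those called cells. Depth per library ranged from 147944805 to 216867549 gene UMIs, and median UMIs per barcode were 4153.5, 2752, 4784, 3388 and 4730.5 in libraries 1 to 5. Guide UMIs numbered 150506, 161218, 167221, 118851 and 257717.

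Whether libraries shared a source was checked from the counts: over the 10 pairs of libraries, Pearson r of log2 CPM across genes was 0.998 to 1.00, chi-square per degree of freedom 7.79 to 104, and 0.738% to 1.07% of barcodes were shared. No pair was therefore taken as a resequenced library. The labels give replicate numbers and no other source, and each library contributed barcodes to both arms of every comparison, so that library entered every model as a block and the comparisons were truly paired. Nothing in the labels says that the libraries came from separate cultures.

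Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, and Scrublet, as in scanpy 1.11.5, removed 3 doublets in all, at automatic score thresholds of 0.500 to 0.619; whether doublets remained was not tested, and keeping doublets therefore changes only 3 barcodes. A barcode was assigned to a guide if it had 3 or more UMIs of exactly 1 guide; barcodes with several guides or none were left out of guide comparisons. This gave 25745 barcodes with 1 guide and 5873 with several. Counts were summed per library and variant. A variant was compared if at least 3 libraries gave 10 or more cells of its arm. The same held for the non-targeting arm where that was the control. All libraries with counts then entered the model, also those with fewer than 10 cells of an arm. The gene tested for a variant was the gene in the guide's name; variant positions were not used here, so that distances from a variant to a gene were not computed. Gene positions came from GENCODE 29, in which 34616 gene identifiers were found.

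Clusters were formed in scanpy from log-normalized counts of 2000 highly variable genes, 30 principal components and 15 neighbours, with the Leiden algorithm (leidenalg 0.10.2, igraph 0.11.9) at resolution 0.5. The 147 genes of 12 function lists were left out of clustering, so that their tests between clusters did not reuse the genes that formed the clusters. The tests did reuse the same barcodes, and the genes left out can vary together with those that formed the clusters. The lists were presynapse, glutamate receptor and postsynapse, voltage-gated channel, axon guidance and adhesion, psychiatric genetics, immediate early, integrated stress and ER stress, heat shock, cholesterol synthesis, glycolysis and hypoxia, interferon response and p53 response. They were chosen from general knowledge. The 88 marker genes of 13 lists covered neuron, glutamatergic, GABAergic, peripheral or sensory neuron, progenitor, pluripotent, cycling, astrocyte, oligodendrocyte, microglial, mesenchymal, endothelial and epithelial kinds. A cluster was compared if at least 3 libraries gave 20 or more of its barcodes, and all 5 libraries then entered its model, including library 4 with 10 barcodes of cluster 8.

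Summed counts were compared with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test, library as block) under R 4.3.3 with limma 3.58.1, and p-values were adjusted by Benjamini-Hochberg over the 14 named pairs, over the genes of each variant, or over all function-list tests of all clusters, at 0.05. Function lists were tested with camera at a preset correlation of 0.01 and with an estimated one. Intervals are 95% intervals. Guides as single values were compared by exact permutation. Levels are CPM of summed counts, given as mean and SD over 5 libraries, with 50 CPM as the level for a marker to be named. The genes named in the text followed a rule: each gene in a guide's name; nearby pairs and, per variant, up to 5 genes past the threshold by p; per cluster, from the function-list genes past the threshold with the 5 largest and 5 smallest log2 fold changes; markers at 50 CPM or more and the highest of each list. Some genes that the rule names are left out of the prose.

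The fits were tested on simulated data. Counts were drawn from a negative binomial model at the real mean levels, library sizes and spreads, each gene on its own, with known fold changes in some genes. Other structure between the real arms was not in these counts. For guide arms the fold was applied to the whole arm, as if each barcode held its assigned guide. Wrong guide assignments, which would dilute an effect, were not simulated, so that the shares recovered are upper values for an effect of a guide. At a fold of 2, the edgeR fit recovered 98.4% of changed genes for rs8089270, the largest arm, at 3 or more guide UMIs. For rs1809332, the smallest, it recovered 90.6%. At a fold of 1.5 the shares were 86.6% and 56.7%. At 10 or more guide UMIs they were 95.3% and 77.8% at a fold of 2, and for clusters 6 and 7 they were 87.9% and 61.5%. The unchanged genes called numbered 3 to 16 per simulation.

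Groups, comparisons, thresholds and most alternatives were set before the data were examined. The alternatives were guide calls at 1 or 10 UMIs, all other barcodes with 1 guide as control, a stricter filter of 1000 genes and 10% mitochondrial, doublets kept, no replicate block, DESeq2 1.42.0, no filter on low counts, Leiden resolutions of 0.3 and 1, other scalings of marker levels, and each library left out in turn. Those chosen after the data were seen were deep clusters only, the combinations with 10 or more guide UMIs, guides as replicates, genes within 1 Mb, clusters 2 to 5 against each other, cluster 6 against cluster 7, the removal of cluster 1, and cluster shares at the other Leiden resolutions. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and data.table, version 1.17.8.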

Results

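The series asked whether sites of regulatory variants from a reporter assay of psychiatric risk loci control the genes next to them. CROP-seq, in which the guide RNA is carried on a transcript that single-cell RNA sequencing can read, was applied to human neurons. The neurons came from WTC11, an established induced pluripotent stem cell line, with an inducible NGN2 cassette, a neurogenic transcription factor that drives stem cells towards excitatory neurons. They also expressed dCas9-KRAB, a cutting-deficient Cas9 joined to a repressor domain, which silences the site that a guide binds (CRISPR interference). Live cells positive for the red reporter of the guide construct had been sorted before capture. There were 5 transcriptome libraries and 5 guide-enriched libraries of the same replicate numbers, joined in 5 matrices of unique molecular identifiers (UMIs) over genes and 64 guides. Of the guides, 31 were named for 8 variants at DCC, 23 for 6 variants at RERE, and 10 were non-targeting. Library 1 held 25820 barcodes with 147944805 gene UMIs. Library 2 held 32479 barcodes with 216867549 gene UMIs, and library 3 held 28145 with 198607804. Library 4 held 21682 barcodes with 178884620 gene UMIs, and library 5 held 27246 with 181741271. Of the 135372 barcodes, 134958 were kept.

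The first question was which kinds of cell the cultures held. All 12 neuron markers were at 50 or more CPM, counts of the summed kept barcodes scaled to a common total. Neurofilament NEFM stood at 3134 ± 88.7 CPM, the growth-associated STMN2 at 2439 ± 199 CPM, tubulin TUBB3 at 1858 ± 50.4 CPM and the dendritic MAP2 at 1031 ± 22.0 CPM (SD, n = 5 libraries). The vesicular glutamate transporter SLC17A6 stood at 483 ± 32.4 CPM and the AMPA receptor subunit GRIA2 at 72.0 ± 2.60 CPM (SD, n = 5), while the highest marker of GABAergic neurons, GAD1, stood at 0.898 ± 0.0589 CPM (SD, n = 5). The transcription factors ISL1 and POU4F1, listed as markers of peripheral or sensory neurons, were at 156 ± 6.76 and 142 ± 8.90 CPM (SD, n = 5). The progenitor marker VIM and the astrocyte marker SLC1A2 were at 675 ± 16.9 and 101 ± 1.80 CPM (SD, n = 5), and 18 of all 88 markers were past 50 CPM. DNMT3B, the highest pluripotency marker, stood at 5.15 ± 0.469 CPM, CCNB1, the highest cycling marker, at 2.74 ± 0.0616 CPM, and the highest endothelial marker, VWF, at 0.903 ± 0.116 CPM (SD, n = 5). MBP led the oligodendrocyte list at 10.1 ± 0.161 CPM, P2RY12 the microglial list at 11.2 ± 1.14 CPM, ACTA2 the mesenchymal list at 15.4 ± 1.82 CPM and EPCAM the epithelial list at 3.53 ± 0.149 CPM (SD, n = 5). Both genes named in the guides were transcribed: RERE, a nuclear co-regulator of the atrophin family, at 1234 ± 73.2 CPM, and DCC, a netrin receptor that steers axons, at 130 ± 9.03 CPM (SD, n = 5). No test applied, since the labels give a single group.

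The second question was how the barcodes divided and where the guides lay. Clustering on genes outside the function lists gave 8 clusters, each with all 12 neuron markers at 50 or more CPM. Cluster 1 held 51.5% ± 14.4 of kept barcodes (SD, n = 5), with 75.8% in library 4 and 41.3% to 53.2% in the others. It was shallow, with a median of 2168 gene UMIs per barcode against 8206 in cluster 2, and 1.07% of its UMIs were mitochondrial on the median against 6.91% there. The nuclear transcript MALAT1 stood at 15.4 ± 2.68 UMIs per barcode in cluster 1, of 2255 UMIs, and at 411 ± 199 in cluster 2, of 11111 (SD, n = 5). Clusters 2, 3, 4 and 5 held 22.8% ± 7.20, 8.07% ± 2.24, 7.44% ± 2.28 and 6.48% ± 1.60 of barcodes (SD, n = 5). Cluster 6 held 2.88% ± 0.883 and cluster 7 held 0.723% ± 0.232 (SD, n = 5), at medians of 30324.5 and 18399 gene UMIs. Cluster 8 held 133 barcodes, or 0.0966% ± 0.0351 (SD, n = 5). A guide at 3 or more UMIs was found in 96.5% ± 1.2 of cluster 6 and 89.8% ± 3.14 of cluster 7, against 30.7% ± 8.12 of cluster 2 and 13.1% ± 3.41 of the shallow cluster 1 (SD, n = 5). At 10 or more UMIs the shares were 82.7% ± 2.43 in cluster 6, 1.66% ± 1.42 in cluster 2 and 0.0353% ± 0.0285 in cluster 1 (SD, n = 5). Scrublet called only 3 doublets, 0 of them in libraries 1, 2 and 3, and its score was highest on the median in cluster 7 (0.167) and cluster 6 (0.0839), against 0.0762 in cluster 1; whether doublets remained among the deep barcodes was not tested.

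**Figure D1:**
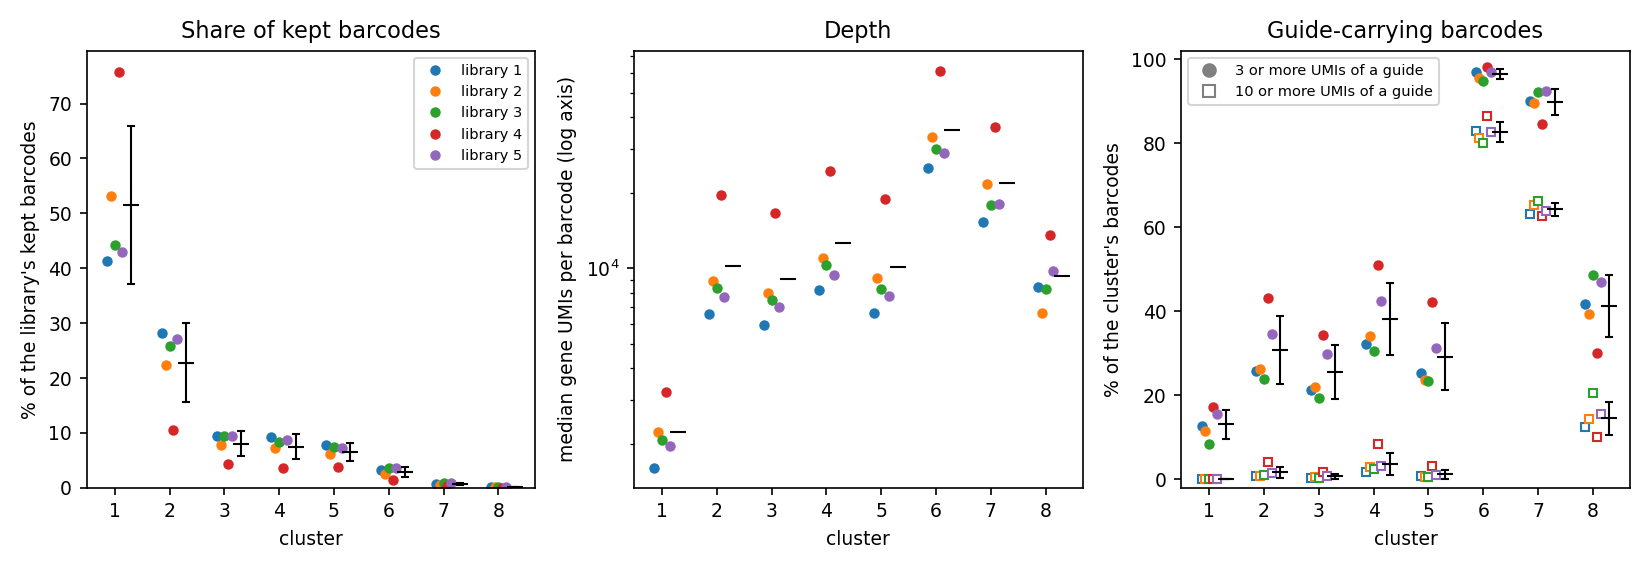
Share of kept barcodes (% of each library), median gene UMIs per barcode (log axis) and share of barcodes with a guide (% of each cluster) for the 8 clusters. Points are the 5 libraries and black lines the mean, with SD bars for the shares; library 4 had the highest share of cluster 1, 75.8%, and clusters 6 and 7 held the guide in most barcodes at either UMI minimum.

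The main comparison asked whether guides at a variant changed the gene in their name. At 3 or more UMIs, 25745 barcodes carried exactly 1 guide, and their levels of DCC and RERE stayed close to those of the 2536 barcodes with a non-targeting guide. DCC, on chromosome 18 from 52340172 to 53535903 (hg38, plus strand), stood at 126 ± 13.0 CPM with non-targeting guides (SD, n = 5). With the 8 sets of DCC guides its log2 fold change ranged from -0.10 with rs4614799 guides (SE 0.047) to 0.18 with rs4513167 guides (SE 0.086). RERE, on chromosome 1 from 8352397 to 8817643 (minus strand), stood at 1275 ± 56.8 CPM with non-targeting guides (SD, n = 5). Its log2 fold change ranged from -0.03 (SE 0.051) with rs1463052 guides to 0.07 (SE 0.059) with rs1809332 guides.

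None of the 14 pairs of variant and named gene passed an adjusted p of 0.05 in the edgeR quasi-likelihood test with library as a block (Benjamini-Hochberg over the 14 pairs). At an unadjusted p of 0.05, 4 pairs passed, all at DCC: rs4513167, rs4614799, rs11877032 at a log2 fold change of 0.17 (SE 0.059, adjusted p = 0.0511) and rs6508210 at 0.16 (SE 0.051, adjusted p = 0.0511). Without the block, 0 pairs were called and 0 had an unadjusted p under 0.05, and DESeq2 called 0 with 1 such pair. Against all other barcodes with 1 guide, 1 pair was called, and it was lower (edgeR adjusted p = 0.0132). In the blocked fit against non-targeting guides, the 95% intervals reached down to a decrease of 12.6% for DCC and 8.65% for RERE. A larger drop on the average of the barcodes counted was outside the intervals of that fit alone. The lowest bound was a log2 fold change of -0.19 there, -0.27 without the block and -0.24 with DESeq2. It was -0.42 at 10 or more guide UMIs. In clusters 6 and 7 alone it was -0.60 at 10 or more and -0.93 at 3 or more. Larger drops were thus not excluded where guide UMIs were many. The barcodes counted at 3 or more UMIs were mostly shallow in guide UMIs: 32.2% lay in cluster 1 and 29.7% in cluster 2, and 9.52% in the deep clusters 6 and 7. Leaving out library 2 gave 2 calls (rs4614799 at -0.14, adjusted p = 0.044, and rs10164055 at 0.24, adjusted p = 0.00473), and leaving out library 1, 3, 4 or 5 gave 1 each, namely rs6508210 (0.18), rs11877032 (0.24), rs6508210 (0.19) and rs4513167 (0.31).

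At 10 or more guide UMIs, 4340 barcodes had exactly 1 guide at that level, 79.7% of them in clusters 6 and 7. Further guides under 10 UMIs were not counted. In clusters 6 and 7, 3459 barcodes had 1 guide at 10 or more UMIs, but 2450 had 1 guide at 3 or more and 2244 had several. Many barcodes in these arms thus carried another guide at 3 or more UMIs. In these arms DCC was higher with rs6508210 guides. Its level was 132 ± 29.3 CPM against 82.9 ± 16.7 CPM with non-targeting guides (SD, n = 5), higher in 5 of 5 libraries. The log2 fold change was 0.67 (95% interval 0.42 to 0.91, edgeR adjusted p = 0.000145 over 14 pairs), the only call, and 2 pairs had an unadjusted p under 0.05. DESeq2 gave 0.67 with adjusted p = 0.0522, and guides as replicates in edgeR gave 0.54 (SE 0.15, adjusted p = 0.0173). With each guide as a single value, the 4 guides of rs6508210 spanned 98.0 to 145 CPM and the 9 non-targeting guides 55.4 to 132 CPM (exact permutation test over 715 arrangements, p = 0.0867, adjusted p = 0.607). The estimates for DCC were also positive with all 6 sets of RERE guides, from 0.07 to 0.47, and 1 was called, rs1934138 at 0.45 (SE 0.12, edgeR adjusted p = 0.0132 over the 14 pairs of guides with the other gene). Of the others, rs1809332 (0.47, adjusted p = 0.0811) and rs301796 (0.30, adjusted p = 0.0753) had an unadjusted p under 0.05. Against all other barcodes with 1 guide, rs6508210 gave 0.55 (SE 0.080, adjusted p = 3.63e-06). With that control 2 of the 14 pairs were called, 1 higher and 1 lower, and estimates reached down to -0.30. In the same exact test, RERE with the 4 guides of rs301804 stood at 810 ± 23.9 CPM (SD, n = 4 guides) against 885 ± 41.8 CPM (SD, n = 9 guides), p = 0.0028 and adjusted p = 0.0392. With library as a block, that pair gave -0.08 (SE 0.066, adjusted p = 0.656) at 10 or more UMIs and 0.05 (SE 0.044, adjusted p = 0.435) at 3 or more, and with guides as replicates -0.12 (SE 0.059, adjusted p = 0.363).

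**Figure D2:**
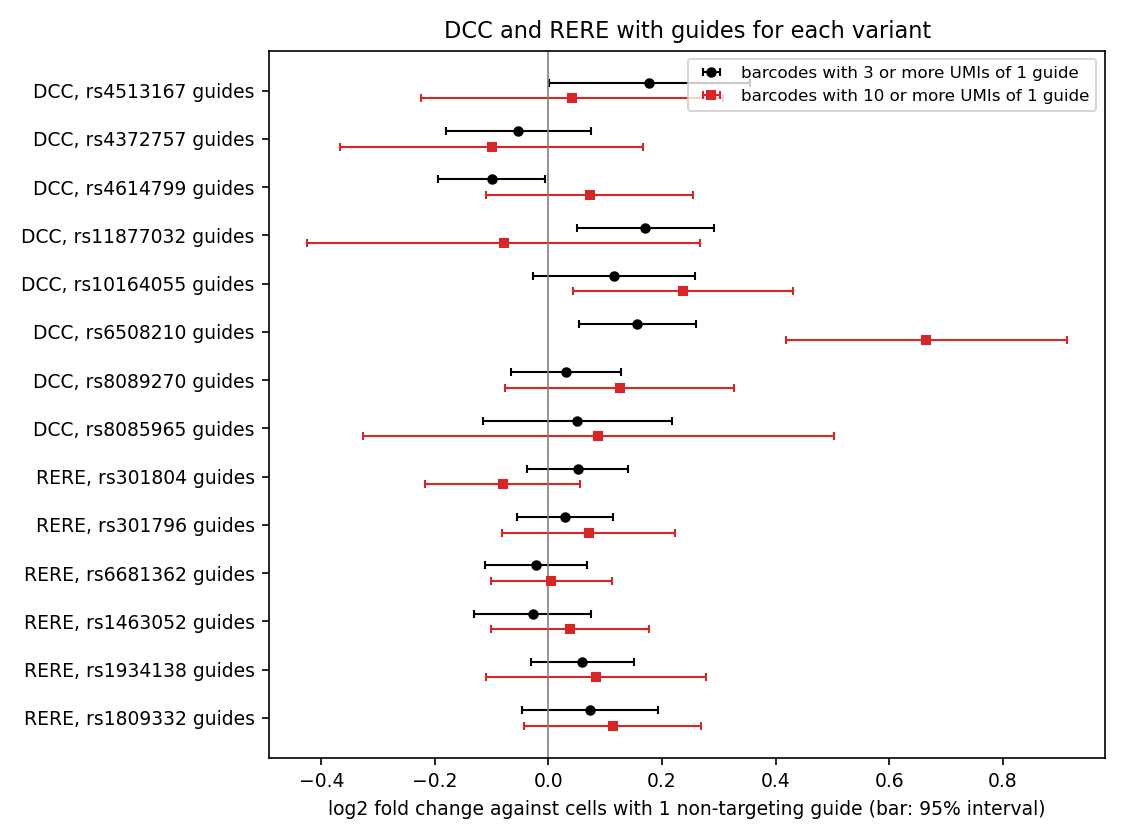
Log2 fold change of DCC or RERE with the guides of each variant against non-targeting guides, with 95% intervals from edgeR over 5 libraries, at 3 or more (black) and 10 or more (red) UMIs of 1 guide. At 3 or more UMIs the estimates lie between -0.10 and 0.18; at 10 or more, DCC with rs6508210 guides lies at 0.67.

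A comparison chosen after the data were seen took in the genes within 1 Mb of DCC or RERE, 120 pairs in all. The long noncoding RNA LINC01630, on chromosome 18 from 51346249 to 51643939 (plus strand), was higher with rs4513167 guides (1.71, SE 0.24, edgeR adjusted p = 1.33e-05 over the 120 pairs) and with rs4614799 guides (1.22, SE 0.21, adjusted p = 3.44e-05). These were the 2 calls, and 9 pairs had an unadjusted p under 0.05. Neither was called over all genes against all other barcodes with 1 guide (0.94, adjusted p = 0.743, and 0.38, adjusted p = 1.00), and the non-targeting arm itself was lower in LINC01630 than all other barcodes with 1 guide (-0.97, SE 0.14, edgeR adjusted p = 0.000548 over 19608 genes). At 10 or more guide UMIs, 0 of 92 pairs were called in edgeR and 7 had an unadjusted p under 0.05, the lowest adjusted p being 0.0616 for LINC01630 with rs4614799 guides (1.05, SE 0.26).

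The next question was which other genes differed with any guide. At 3 or more UMIs, 32 pairs of variant and gene passed an adjusted p of 0.05 (edgeR, adjusted over the 13815 to 15464 genes tested per variant), 16 higher and 16 lower, over 24 genes and 11 variants. DLC1 was lower with 5 variants, by log2 fold changes from -0.68 (SE 0.12, rs4614799) to -1.07 (SE 0.16, rs6681362). Against all other barcodes with 1 guide, none of the 5 was called (-0.10 to -0.51, adjusted p = 0.319 to 1.00), and the non-targeting arm was higher in DLC1 than those barcodes (0.67, SE 0.095, adjusted p = 0.000244). RELN, a secreted protein that guides migrating neurons, was higher with rs301796 (0.71, SE 0.12) and rs1463052 (0.69, SE 0.13). LINC01630 was higher with rs4513167 (adjusted p = 0.0016) and rs4614799 (adjusted p = 0.00874) over all genes too. FSTL5 was higher with rs4513167 and rs1809332, and AL136962.1 was lower with rs301796 and rs1934138. Among genes called with 1 variant, the adhesion molecule DSCAM (0.50) and KIAA1217 (0.71) were higher with rs4513167, and the nuclear receptor NR2F1 (1.95) and the Wnt carrier WLS (1.09) with rs4372757. The growth factor PTN (0.39) and the muscarinic receptor CHRM2 (0.66) were higher with rs301804, and the noncoding CASC15 (0.56) with rs6681362. AL591501.1 (0.68) was higher with rs6681362 and AL590550.1 (0.75) with rs1934138. Lower were AC012494.1 (-0.43), AC114316.1 (-0.69) and AC021351.1 (-1.72) with rs301804, AC069277.1 (-0.87) and GRM7-AS3 (-1.06) with rs1463052, and AC040174.1 (-0.88) with rs1934138. SGCZ (-0.45) was lower with rs8085965, and the calcium sensor SCGN (-0.65) and AC138305.1 (-0.57, adjusted p = 3.91e-05, the smallest) with rs1934138.

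Of the 202642 tests, 5.05% had an unadjusted p under 0.05. Every comparison shares the non-targeting arm: the mean correlation between the log2 fold changes of pairs of variants, across genes, was 0.375, against 0.381 in counts simulated with no effect of any variant. The simulated counts gave 0 calls, but mixed real arms did not. Of the 16 ways to swap the arms within libraries, the real one among them, 9 gave at least 32 calls, and the highest other gave 75. The 32 calls were thus no more than mixed arms gave. Against all other barcodes with 1 guide, 17 of the 32 calls were still called with the same sign, among them both of AL136962.1 and that of FSTL5 with rs1809332. The non-targeting arm differed from those barcodes in 7 of 19608 genes (edgeR), among them DLC1, LINC01630, RELN (-0.44, SE 0.076) and CASC15 (-0.36, SE 0.072). Without library 2, 3 or 5 there were 69, 56 or 68 calls, without the block 2, with DESeq2 6, and without a filter on low counts 326. At 10 or more guide UMIs there were 9 calls, 8 lower, and no pair was called at both minimums. Of 29 pairs called at 3 or more UMIs and tested at 10 or more, 25 had the same sign there and 14 an unadjusted p under 0.05. The 9 calls included the neuropeptide SST (-1.06, SE 0.12, rs1809332), KCNIP4 (-0.56) and INPP4B (-1.11) with rs8085965, IGFBP2 (-1.02) with rs4614799, AL583808.1 with 3 variants, ADARB2 (-0.57) and DISC1FP1 (1.79). Without library 1, 2, 3, 4 or 5 this count was 55, 23, 41, 18 or 23.

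The cluster comparisons asked how the clusters differed in synaptic, channel, guidance and stress genes, none of which had been used to form the clusters. Between them, 1013 of 1176 tests of the 147 function-list genes passed an adjusted p of 0.05 (edgeR, library as block, adjusted over all clusters), 431 higher and 582 lower. The clusters were formed from the same barcodes, by genes that can vary together with these. A high share of calls was thus largely set by the clustering and is not particular to these lists. The share over all genes is not given here. In the shallow cluster 1, most stress genes were higher than in all other barcodes and most guidance and channel genes lower. Cluster 1 also differed in RNA composition. MALAT1 was low there, and RERE stood at 245 ± 15.1 CPM against 1728 ± 37.6 CPM in cluster 2 (SD, n = 5). The genes with the largest folds over all other barcodes included NDUFB4 (4.24) and RPS20 (4.13). For the lists in cluster 1, a difference in cell state was not told apart from RNA composition. DDIT3, a transcription factor of the unfolded protein response, was higher by a log2 fold change of 2.15 (SE 0.064), the mitophagy gene BNIP3 by 2.06 (SE 0.050), GADD45A by 2.05 (SE 0.050), the small heat shock protein HSPB1 by 1.97 (SE 0.053) and DDIT4 by 1.96 (SE 0.065). CSMD1, a complement regulator (-3.45), IFIT1 (-3.45), the calcium channel CACNA1C (-3.23), the semaphorin SEMA6D (-3.21) and the postsynaptic scaffold DLG2 (-3.18) were lower. All 8 p53 response genes were higher, 8 when adjusted over the list alone (camera adjusted p = 0.0047 with the preset correlation, adjusted p = 0.512 with an estimated correlation). All 8 glycolysis and hypoxia genes were higher too, 8 when adjusted over the list alone (camera adjusted p = 0.00382, and adjusted p = 0.512 with an estimated correlation). Of 16 axon guidance genes, 15 were lower and 1 higher, and all 16 were called when adjusted over the list alone (camera adjusted p = 0.00121, and adjusted p = 0.512 with an estimated correlation). Of 18 voltage-gated channel genes, 16 were lower and 2 higher, with 18 called when adjusted over the list alone (camera adjusted p = 0.00178, and adjusted p = 0.512 with an estimated correlation).

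Further lists separated cluster 1 as well. Of 22 psychiatric genetics genes, 18 were lower and 3 higher, 21 called when adjusted over the list alone (camera adjusted p = 0.0047, and adjusted p = 0.512 with an estimated correlation). Of 10 genes of the integrated and ER stress response, 9 were higher and 1 lower, 10 when adjusted over the list alone (camera adjusted p = 0.0054, and adjusted p = 0.512 with an estimated correlation). All 5 heat shock genes were higher, 5 when adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.512 with an estimated correlation). Of 20 glutamate receptor and postsynapse genes, 14 were lower and 5 higher, 19 when adjusted over the list alone, and the list as a whole missed the threshold (camera adjusted p = 0.068). So did the 18 presynaptic genes, 11 higher and 7 lower, 18 when adjusted over the list alone (camera adjusted p = 0.316).

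Each of clusters 2 to 5 was first compared with all other barcodes, as planned, so that the shallow cluster 1 was part of the reference. RNA composition differed here too. Ribosomal protein UMIs per barcode were 279 of 14285 in cluster 4, against 251 of 2255 in cluster 1 and 2517 of 36656 in cluster 6 (means over 5 libraries). A difference in cell state was not told apart from RNA composition. GRM5 (1.67, SE 0.059) and the sortilin-family receptor SORCS3 (1.29, SE 0.050) were higher in cluster 2 and FOXP2 (-2.19, SE 0.063) lower. In cluster 3, NTN1 (2.05, SE 0.065) and DCC (1.54, SE 0.059) were higher and the synaptic adhesion gene NRXN3 (-1.41, SE 0.051) lower. CSMD1 (2.08, SE 0.044) was higher in cluster 4 and VAMP2 (-1.51, SE 0.044) lower. In cluster 5, KCNQ3 (1.82, SE 0.039) and NPAS4 (1.66, SE 0.15) were higher and BCL11B (-1.41, SE 0.090) lower. Of the 147 genes, edgeR called 133 in cluster 2 (56 higher, 77 lower), 124 in cluster 3 (47 higher, 77 lower), 130 in cluster 4 (43 higher, 87 lower) and 126 in cluster 5 (57 higher, 69 lower).

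Clusters 2 to 5, of similar depth, were also set each against the other 3, a comparison chosen after the data were seen. Cluster 5 was separate from cluster 2 at Leiden resolutions of 0.5 and 1 only. With doublets kept, at a resolution of 0.3 and with the stricter filter, 89.8%, 89.0% and 84.8% of its barcodes lay in the cluster that best matched cluster 2. Cluster 2 had more of the sodium channel SCN1A (1.13, SE 0.016), the transcription factor TCF4 (1.02, SE 0.023) and the adhesion molecule NLGN1 (0.91, SE 0.0061). It had less of the transcription factor FOXP2 (-2.64, SE 0.037) and of the AMPA receptor subunit GRIA1 (-2.07, SE 0.025). Cluster 3 had more NTN1, the netrin ligand (1.73, SE 0.047), and more of its receptor DCC (1.19, SE 0.018), at 325 ± 26.5 CPM against 115 ± 5.87 in cluster 2 (SD, n = 5). It had less CSMD1 (-2.72, SE 0.022) and less UNC5C, another netrin receptor (-2.60, SE 0.020). Cluster 4 had more CSMD1 (2.56, SE 0.014), and less of the Slit receptor ROBO1 (-1.46, SE 0.016), the potassium channel KCND2 (-1.43, SE 0.016) and NLGN1 (-1.34, SE 0.015). Cluster 5 had more of the activity-induced factors NPAS4 (1.62, SE 0.16) and FOSB (1.17, SE 0.11), at 1.82 ± 0.257 and 3.50 ± 0.756 CPM, and of the channels KCNQ3 (1.53, SE 0.017) and KCND2 (1.21, SE 0.017). In cluster 5, 9 of 10 immediate early genes were higher and 0 lower, 9 when adjusted over the list alone (camera adjusted p = 4.7e-05, and adjusted p = 0.332 with an estimated correlation). In cluster 4, 9 of 10 were lower, 9 when adjusted over the list alone (camera adjusted p = 0.00551, and adjusted p = 0.462 with an estimated correlation). All 10 cholesterol synthesis genes were higher in cluster 2, 10 when adjusted over the list alone (camera adjusted p = 0.000371, and adjusted p = 0.462 with an estimated correlation).

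**Figure D3:**
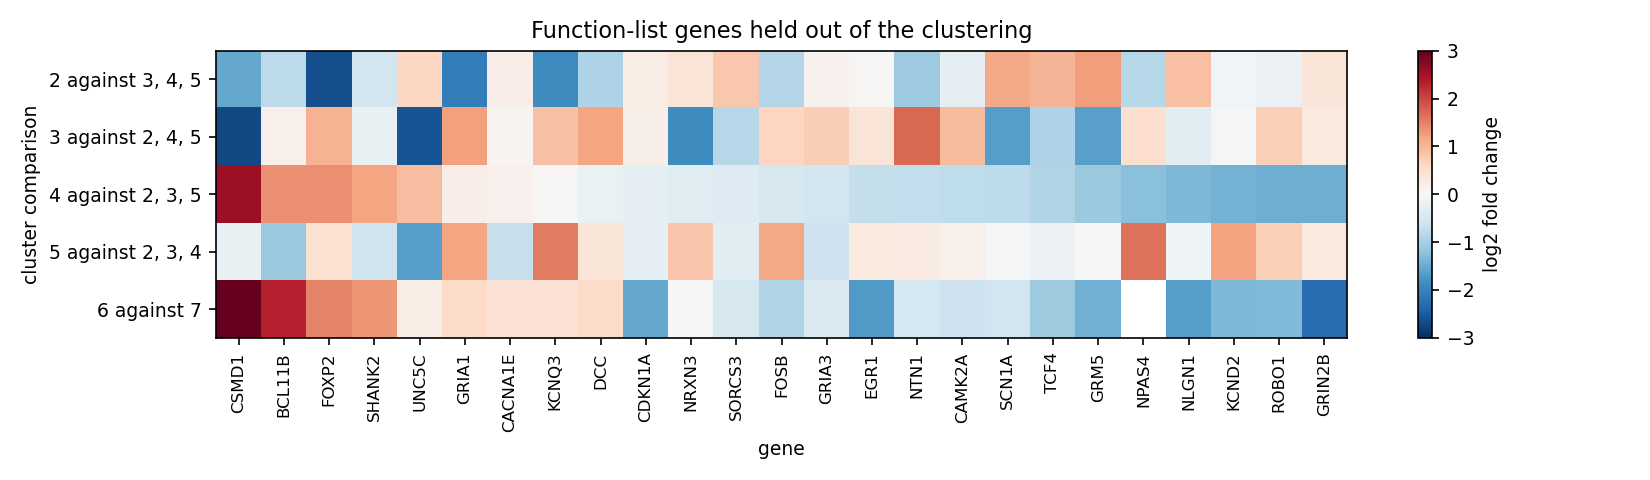
Log2 fold change (colour) of function-list genes in clusters 2 to 5, each against the other 3, and in cluster 6 against cluster 7 (edgeR over 5 libraries; NPAS4 was not tested in the last and is left white). CSMD1, BCL11B, FOXP2 and SHANK2 are higher both in cluster 4 and in cluster 6.

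The deep clusters 6 and 7, where nearly all barcodes carried a guide, were compared with each other in the same way. Their division was lost at a Leiden resolution of 0.3 and with the stricter filter. There 98.5% and 97.7% of the barcodes of cluster 7 lay in the cluster that best matched cluster 6. Cluster 6 had more CSMD1 (3.05, SE 0.028), the transcription factor BCL11B (2.33, SE 0.20), FOXP2 (1.48, SE 0.15) and the scaffold SHANK2 (1.33, SE 0.091). It had less of the NMDA receptor subunit GRIN2B (-2.28, SE 0.35), at 0.469 ± 0.163 CPM, and of EGR1 (-1.70, SE 0.074) and NLGN1 (-1.66, SE 0.057). All 10 cholesterol synthesis genes were lower in cluster 6 than in cluster 7, 10 when adjusted over the list alone (camera adjusted p = 8.77e-05, and adjusted p = 0.235 with an estimated correlation). Against all other barcodes, whose RNA composition differed, cluster 6 had more BCL11B (1.92, SE 0.059), and less KCND2 (-2.16, SE 0.065) and ROBO1 (-2.02, SE 0.075). Cluster 7 had more of the stress genes CHAC1 (1.33, SE 0.19) and JUN (1.15, SE 0.070) and less CSMD1 (-1.90, SE 0.082). Of 147 genes, 118 were called in cluster 6, 60 higher and 58 lower, and 122 in cluster 7, 64 higher and 58 lower.

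Cluster 8, the 133 barcodes, of which library 4 gave 10, held transcripts of cycling cells: TOP2A stood at 317 ± 99.5 CPM, UBE2C at 166 ± 77.8 CPM, CCNB1 at 109 ± 23.3 CPM and MKI67 at 93.8 ± 46.2 CPM (SD, n = 5). Among progenitor markers, FABP7 stood at 394 ± 200.1 CPM and SOX2 at 139 ± 24.5 CPM, beside NEFM at 1125 ± 248 CPM (SD, n = 5). The angiogenic factor VEGFA (4.71, SE 0.54), the cell cycle inhibitor CDKN1A (4.62, SE 0.41) and NTN1 (4.26, SE 0.17) were higher than in all other barcodes, and CSMD1 was lower (-3.14, SE 0.21). GRIN1 was at 0 counts there, and no fold is given. All 18 presynaptic genes were lower, 18 when adjusted over the list alone (camera adjusted p = 0.0047, and adjusted p = 0.512 with an estimated correlation). Of its 8 p53 response genes, 7 were higher, 7 when adjusted over the list alone (camera adjusted p = 0.000201, and adjusted p = 0.512 with an estimated correlation).

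Across the 8 clusters and 12 lists, 58 of 96 camera tests passed with the preset correlation of 0.01, 27 higher and 31 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.512, with 2 unadjusted p under 0.05). The interferon response list passed in no cluster, with 4 of its 7 genes called in cluster 1, 2 higher and 2 lower. The barcodes that entered cluster 1 depended on the clustering: with the 3 doublets kept, the best matching cluster held 31.2% of barcodes in place of 51.5%, and at a Leiden resolution of 1 it held 27.2%. A further large cluster appeared in both settings, and its share differed strongly between libraries. With doublets kept it held 20.3% on the mean, from 2.33% to 66.7% of a library. At a resolution of 1 it held 24.0%, from 3.92% to 70.7%. Clustering made no correction for library. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries.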

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

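The tests of free RNA, of repeated counting of a guide molecule and of the non-targeting arm for genes called with several variants or with 1 were chosen after the results were seen; the other tests in this part were set before. Of 52 groups of 5 libraries examined, 11 had a library far from the others by Dixon's test, while chance marks about 1 in 20 groups, or 2.6 of 52.

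Library 4 stood apart in median gene UMIs per barcode: 19536 in cluster 2 (6614 to 8904.5 in the others), 16700 in cluster 3, 24388 in cluster 4, 18940 in cluster 5 and 61317 in cluster 6. Library 4 was also highest for INA at 576 CPM, DCX at 489 CPM, SLC17A6 at 541 CPM and POU4F1 at 157 CPM. GRIA2 was highest in library 1, at 76.7 CPM. Guide UMIs per barcode were highest in library 5, at 9.46.

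A shallow cluster 1 held 51.5% of kept barcodes. Free RNA in droplets without a cell would give guide pairs at random. Pairs of guide UMIs in 1 barcode named the same guide 7.12 times as often as the pooled profile gives. That argues against free RNA with each molecule counted once as the whole account. Repeated counting of a guide molecule would add same-guide pairs too. At equal guide UMIs the share of same-guide pairs was 1.52 times that of clusters 2 to 5 (SD of the ratio 0.129). However, guide UMIs per barcode were fewer in cluster 1, 3.33 against 5.73 to 7.68 (means over 5 libraries). At equal totals a repeated count is likelier where molecules are fewer, so that the ratio cannot decide. Repeated counting, also of free RNA, stays open. Pieces of single cells stay open, with an extra-Poisson variance of 0.0331 between the bounds set. The design names no group here, so no biological explanation was tested.

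Barcodes of clusters 2 to 5 carried few guide UMIs although cells had been sorted for the guide's reporter. Cells without a guide would lack guide UMIs more than cytosolic transcripts, yet relative to cluster 6, and over the level of cluster 1, their guide UMIs were 15.1 times their ribosomal protein UMIs (5.97 to 19.5 over the libraries). That ratio has a small denominator, 0.481% ± 0.339 of cluster 6 (SD, n = 5). Without subtracting cluster 1 the ratio was 1.1 ± 0.105 (SD, n = 5), from 11.5% and 10.5% of cluster 6. Ribosomal protein UMIs per barcode were 258 to 279 in clusters 2 to 5, close to the 251 of cluster 1. The subtracted ratio thus rests on almost no ribosomal signal, and the other compares levels near that of cluster 1. A loss of cytoplasmic RNA needs a ratio near or over 1, which both values met. For the reason given, neither value can decide between that loss and cells without a guide. Both stay open, and no biological explanation was tested.

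The same genes were called against the non-targeting arm for several variants. Against all other barcodes with 1 guide 53.1% of the 32 calls held, 23.1% for genes called with 2 or more variants and 73.7% for genes called with 1, but a deviation of the shared arm itself makes genes recur, so that these shares cannot decide whether the non-targeting arm stands apart. That arm differed from all other barcodes in DLC1, LINC01630, RELN and CASC15, of which no call held, and may account for those. It does not account for the calls that held, such as both of AL136962.1 (-0.98 with rs1934138 and -1.16 with rs301796). Single non-targeting guides set against the other non-targeting guides gave 0.535 times as many calls as a variant did, so that differences between cells of single guides, whatever they target, stay open. An effect of the variants themselves was not separated from these.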

How the results depend on the processing

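The alternatives with deep clusters only, with 10 or more guide UMIs combined with another change, with guides as replicates, within 1 Mb, between subsets of clusters, and of cluster shares at other Leiden resolutions were chosen after the results were seen. The cause of a difference was not tested unless stated.

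For the 14 named pairs, 0 were called in edgeR (4 at an unadjusted p under 0.05), and 0 with 1 or more guide UMIs, with doublets kept, with no replicate block and with DESeq2. The count was 1 with 10 or more guide UMIs (higher) and 1 against all other barcodes with 1 guide (lower). It was 2 with the stricter cell filter and 3 without a filter on low counts, all higher, and 1 to 2 without a replicate. Within 1 Mb, a different set of 120 pairs, it was 2, both LINC01630. In deep clusters it was 1 at 10 or more UMIs (higher) and 2 at 3 or more (1 higher and 1 lower, with estimates down to -0.56). With 10 or more UMIs the count was 2 against all other barcodes (1 higher and 1 lower), 1 with no replicate block and 1 with guides as replicates. It was 0 with DESeq2, and 2, 1, 1, 1 and 1 without replicates 1 to 5.

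Over all genes, 32 pairs were called. The count was 9 with 10 or more guide UMIs, 67 against all other barcodes, 2 with no replicate block, 6 with DESeq2, 326 without a filter on low counts, and 37 to 69 without a replicate. With 10 or more UMIs it was 5 in deep clusters, 77 against all other barcodes, 2 with no replicate block, 3 with DESeq2, 1 with guides as replicates, 55 without replicate 1 and 18 without replicate 4. It was 30 with 1 or more UMIs, 34 with the stricter filter, 32 with doublets kept and 35 in deep clusters at 3 or more UMIs.

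Between clusters, 1013 tests were called, 775 to 1461 under the other settings (82.8% to 88.0% of 882 to 1764 tests, against 86.1%) and 966 to 1052 without a replicate. Clusters 2 to 5 against each other gave 421 and cluster 6 against cluster 7 gave 118, from fewer tests (585 and 144). Of 96 camera tests 58 passed, 59 with no replicate block, and 0 with an estimated correlation. Cluster 1 held 51.5% of barcodes, 34.5% with the stricter filter, 31.2% with doublets kept, 27.2% at Leiden resolution 1, 51.5% at 0.3, and 45.4% to 54.0% without a replicate. The lower shares are of the best matching cluster alone. A further cluster held 17.0% with the stricter filter (1.62% to 61.2% over libraries), 20.3% with doublets kept and 24.0% at resolution 1. All settings gave 18 markers at 50 CPM or more.

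Signs changed as follows. With 1 or more guide UMIs, DCC was at -0.36 (rs4513167), -0.31 (rs11877032), -0.014 (rs10164055), -0.0044 (rs6508210), -0.16 (rs8089270) and -0.036 (rs8085965), and RERE at -0.0065 (rs301804), -0.085 (rs301796) and -0.037 (rs1934138). Of 9 called genes that changed sign there, 8 are given: DSCAM was at -0.25, KIAA1217 at -0.46, FSTL5 with rs4513167 at -0.022, SGCZ at 0.27, AL591501.1 at -0.43, CASC15 at -0.091, AC069277.1 at 0.32 and AC138305.1 at 0.29. With 10 or more, DCC was at 0.073 (rs4614799) and -0.078 (rs11877032), RERE at -0.080 (rs301804), 0.0053 (rs6681362) and 0.038 (rs1463052), DLC1 with rs4372757 at 0.084, WLS at -0.33, RELN with rs301796 at -0.028 and AC138305.1 at 0.24. Against all other barcodes, DCC with rs8089270 was at -0.017. Without a replicate, DCC lay at -0.14 to 0.011 (rs4372757), -0.017 to 0.072 (rs8089270) and -0.056 to 0.16 (rs8085965), and RERE at -0.040 to 0.00069 (rs6681362) and -0.055 to 0.018 (rs1463052). RERE with rs301804 was at -0.083 and -0.039 in deep clusters at 10 or more and 3 or more UMIs. With the higher minimum it was at -0.11 against all other barcodes, -0.076 with no replicate block, -0.078 with DESeq2, -0.12 with guides as replicates, and -0.094, -0.11, -0.0035, -0.093 and -0.089 without replicates 1 to 5.

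Of 399 values of called genes under alternatives, 216 kept direction and call, 170 kept direction but lost the call and 13 reversed. Of 204 values of named pairs, 148 kept both, 23 gained a call and 33 reversed. Of 980 values of cluster genes, 974 kept both and 6 lost the call. Of 180 marker levels, 19 moved by more than 1 SD. All 19 moved in the same alternative, the mean over barcodes of counts scaled within each barcode. In that alternative 19 levels moved and 1 did not. The marker levels given from summed counts thus depend on this choice, while 18 markers were at 50 CPM or more with either. The alternative of genes within 200 kb was not run, since variant positions were not used here. Of simulated changes of 1.5-fold applied to a whole arm or cluster, without wrong guide assignments, 56.7% were recovered in the smallest arm and 48.5% in cluster 7.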

Other observations

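The test of clusters 4 and 6, the comparison per guide, the splits over all genes at 10 or more guide UMIs, and the test of cluster shares for genes that lead a cluster, were chosen after the results were seen; the tests of cluster shares over all calls and of the remaining splits were set before.

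Swapping the arms within libraries gave 16 splits, too few for a share under 0.05. Over all genes, 9 of the 16 splits gave at least the real 32 calls, and the highest other split gave 75, which points to a structure of the samples other than the arms, or to a blocked model that calls too many genes on any split; these were not told apart. With no replicate block the real split gave 2 calls, and counts simulated with no effect gave 0 with the block. For the named pairs, 16 of 16 splits gave at least the real 0, the highest other 3. At 10 or more guide UMIs, 9 of 16 gave at least the real 1 call among the named pairs, the highest other 4, and over all genes 13 of 16 gave at least the real 9, the highest other 91, which leaves the same accounts open. For the held-out genes between clusters, 1 of 16 gave the real 1013, the highest other 2. The clusters were formed from these same barcodes, so that this gap was largely fixed in advance and gives no separate support. For the function lists, 1 of 16 gave the real 58, the highest other 45.

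The call of DCC with rs6508210 guides at 10 or more guide UMIs was a rise, the opposite of what silencing an enhancer of DCC would give. Its log2 fold change was 0.67 there and 0.45 to 0.75 without a replicate, but estimates for DCC were also positive with all 6 sets of RERE guides (0.07 to 0.47, 1 called), and another of the 16 splits called 4 pairs. The cause was not tested. LINC01630 was likewise not confined to DCC guides: per guide at 10 or more UMIs it stood at 10.7 ± 7.72 CPM with non-targeting guides, 23.8 ± 22.2 CPM with DCC guides and 24.6 ± 20.9 CPM with RERE guides (SD over guides).

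A hypothesis on the clusters is that the deep cluster 6 and cluster 4 may hold the same kind of neuron at different recovery of cytoplasmic RNA. Of the held-out genes called both in cluster 4 against clusters 2, 3 and 5 and in cluster 6 against cluster 7, 97.2% went the same way (103 of 106). The shares were 22.8%, 43.5% and 23.0% for clusters 2, 3 and 5. Cluster 4 was part of the reference of those clusters, so that their low shares follow in part from its own and are no separate contrast. The libraries and cells are the same ones in which the pattern was seen.

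Of the 24 genes called with guides, 8 were among the genes that lead a cluster, where 0.124 would be expected were all tested genes equally likely to be called. The leading genes were not matched to other genes in level or spread, so that 0.124 may be too low. Differing shares of clusters between arms might have given the calls. Over all 32 calls the shares predicted a median of 0.102 of the observed log2 fold change, which argues against this for the calls as a set, with 2 calls over 0.5, those of NR2F1 (0.844) and of FSTL5 with rs4513167 (0.543). Over the 9 calls of the genes that lead a cluster the median was 0.156 (quartiles 0.132 and 0.225), which leaves it open for these genes, and for NR2F1 the shares may have given most of the difference.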
